A study of Mus musculus with 7 samples.

How the data were processed

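Hippocampal RNA from 7 samples of male wild-type C57BL/6 mice was converted to sequencing libraries with a SMARTer kit, per the labels' protocols. The authors deposited 1 table of FPKM (fragments per kilobase of gene per fixed number of mapped fragments), with 27583 gene names and 7 columns. The unit is taken from the deposited table's own name. The mouse build mm10 is named in the submitters' processing notes. The aligner, the counter, the annotation and any filter are not given in the sources used here. FPKM removes depth and gene length but not differences in RNA composition, so a few abundant genes in a library lower the values of the others. Of the gene names, 26041 matched RefSeq symbols, and gene positions were taken from GENCODE M21 on the same build.

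Each column was matched to a sample by the library name in its description. All samples carried the same labels, so all stand in 1 group and the comparison of injured with healthy animals, with its alternatives, was not run. Condition was never inferred from values or order.

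Depth was estimated from the table. Values of low genes are whole multiples of the worth of 1 read, which gave relative depths of 0.984 to 1.01. RefSeq lengths of 1085 genes seen in 1 library only then placed the median depth at 37939300 reads, a value within 0.3% of that from 52 of those genes. This is an estimate, since the authors' gene lengths are not given in the sources used here. Reads of a gene are quoted only where its value came out whole within 0.02 in each library; they cover counting error only.

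Analyses used log2(FPKM + 1) over the 12052 genes with a median FPKM of at least 1. On this scale the change of low genes is understated. Gap ratios of single genes in the closing section used FPKM itself. Gene lists, 29 in all, were fixed before the data were examined, 1 of them a check of sex-linked genes. Of the listed genes 2 were not found in the table. For each list with at least 5 members left, the median SD (two-sided) and the median pairwise Pearson r (upper one-sided) were compared with 10000 random lists of the same size, each member drawn from the 200 genes nearest in mean level. A p of 0.0001 is the smallest that these random lists can give, before doubling for two-sided tests. Adjusted p-values follow Benjamini and Hochberg at 0.05. Associations with Per2 used exact permutation over all pairings of the 7 libraries, limma-trend, and camera with a preset correlation of 0.01 and with an estimated one, with 100 random reassignments of the Per2 values. Principal components were taken of gene-centred values.

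A measure was treated as falling into separate sets where its largest gap, with at least 2 libraries on each side, took a share of the range above the 95th percentile of 20000 simulated normal sets of 7, which was 0.510. This rule was not part of the design fixed beforehand. Per2 had 0.526, and 4.19% of simulated sets had a gap as large. A higher limit, the 99th percentile (0.633), was tried after the Per2 value had been seen. It would have left Per2 outside the rule, kept its pooled coefficients, and reduced the genes with such a gap from 568 to 95. It was dropped because it had been chosen with the outcome in view, and the 95th percentile stands.

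Named genes follow a rule fixed beforehand: clock list members with a median FPKM of at least 1, the 15 genes with the largest SD, the 10 with the highest median, the 10 with the smallest limma p in each direction for Per2, and in each list the 2 members with the largest SD and the 1 with the smallest. This gave 142 genes, some of which are not reported here. Genes outside it were chosen after their values were seen, among them the further genes quoted in the closing section.

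The limma step was tested on simulated data for 12051 genes: at a slope of 1 it recovered 16% of 100 changed genes and at 0.5 it recovered 0%, with 0 false calls. The list tests on 12052 simulated genes recovered 15 of 15 lists made to share variation, with 1 false call among 110, and 15 of 15 made more variable, with 3 false calls among 110. Exact permutation of r called 96 of 2000 unrelated pairs at 0.05. In the limma and list simulations genes were drawn independently, apart from the changes added, and no library stood apart. Real genes co-varied and replicate 5 stood apart, so those counts of false calls may not carry over. With the real values, 1 of the 100 reassignments of Per2 called 127 genes by limma, while most called 0.

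Alternatives were a pseudocount of 0.1, values rescaled to sum to 1000000, upper-quartile scaling, a median FPKM minimum of 0.1 or 5, leaving out each library in turn, Spearman's rho, limma without the trend, and the number of detected genes as covariate. For r with Per2 only, the 2 libraries farthest from its median were also left out, without a p-value. A filter on mean FPKM of at least 1 was added after seeing the data. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1 were used.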

Results

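RNA of the hippocampus, the brain region that serves memory and mood regulation, was sequenced in 7 libraries from male wild-type C57BL/6 mice. The series set out to compare hippocampus after spinal cord injury with that of healthy animals and names Per2, a repressor in the circadian clock, in its title. The labels of all 7 samples are alike, and neither they nor the column names of the expression table say which animal was injured. The injury-against-control comparison was therefore not made, and all libraries stand in 1 group, hippocampus, as replicates 1 to 7. Values are given per library or as median and range. No label says outright that each library came from a separate animal. P-values computed across libraries therefore measure only the spread between these samples, which may be technical. Those of the tests against random gene lists come from draws of genes and do not measure that spread.

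Expression was given as FPKM for 27583 genes. Between 12007 and 12185 genes reached an FPKM of 1 in a library, with a median of 12102. The step size of low values gave an estimated depth of 37324400 to 38448100 reads per library. Mitochondrially encoded transcripts, which specify respiratory chain subunits, made up 14.5% of all FPKM at the median, from 12.8% in replicate 4 to 17.0% in replicate 5. The 10 genes with the highest median were COX1, CYTB, ND1, ND2, ND4 and ND5 of the mitochondrial genome, the iron storage gene Fth1, the protease inhibitor gene Cst3, the elongation factor gene Eef1a1 and the calmodulin gene Calm2. Pairs of libraries without replicate 5 correlated across genes with a Pearson r of 0.989 to 0.995 on log2(FPKM + 1), and pairs with replicate 5 with 0.976 to 0.983. Genes are not independent replicates in this coefficient. No 2 libraries held identical values. The Y-linked genes Ddx3y (11.1 to 13.9 FPKM) and Kdm5d (4.01 to 4.62 FPKM) were present in each library.

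Per2 was expressed at a moderate level in each library and varied 1.51-fold between the lowest and the highest. Its FPKM was 6.79, 6.87, 5.83, 6.79, 4.53, 4.63 and 5.78 in replicates 1 to 7, with a median of 5.83. The gene lies on the minus strand of chromosome 1, from 91415982 to 91459324 in mm10. Its SD on log2(FPKM + 1) was 0.22, at percentile 88.7 of the 1000 genes nearest in mean level, whose median SD was 0.11. The values correspond to an estimated 1044 to 1593 reads, so that counting error at the lowest library was 3.09%, well below the difference between the lowest and highest libraries.

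**Figure D1:**
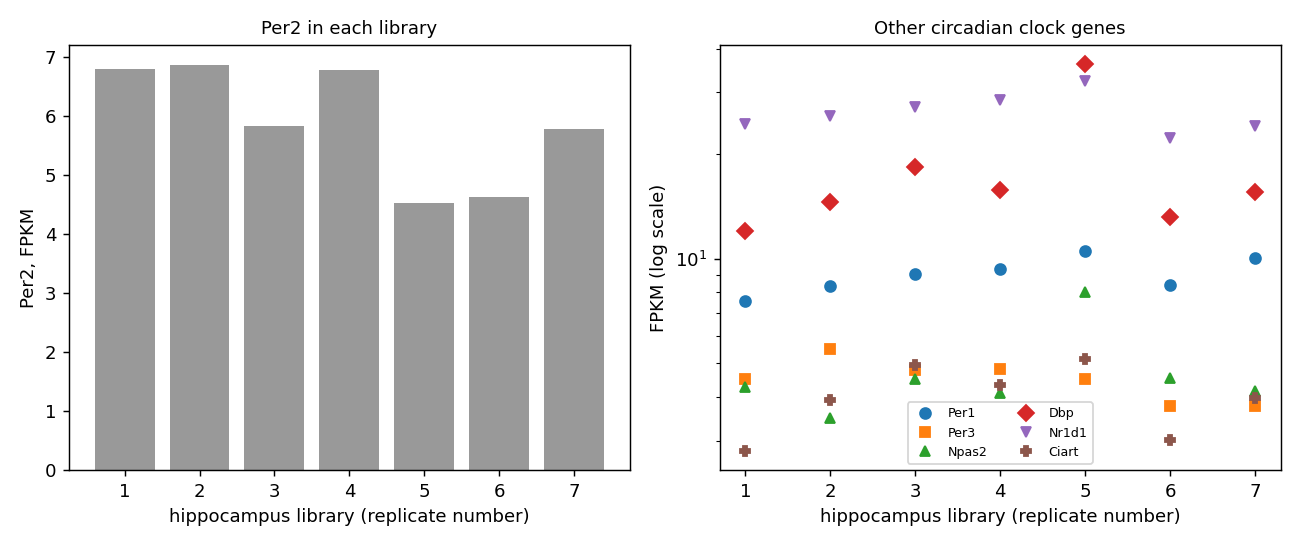
Left, Per2 in FPKM as bars from 0 for each of the 7 hippocampus libraries; right, 6 other circadian clock genes in FPKM on a log axis, 1 symbol per gene. Per2 ran from 4.53 in replicate 5 to 6.87 in replicate 2, and Dbp and Npas2 were highest in replicate 5 at 36.2 and 8.0.

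Most other clock genes had a smaller ratio of highest to lowest library than Per2. Of 24 listed clock genes in the table, 21 had a median FPKM of at least 1. The activators Clock (10.1 to 11.6 FPKM) and Bmal1 (1.37 to 1.92) and the repressor Cry2 (25.7 to 29.6) stayed within narrow ranges. The kinase genes Csnk1d (29.3 to 36.1) and Csnk1e (8.36 to 10.05) and the output factor genes Tef (40.9 to 52.2) and Hlf (22.7 to 30.5) varied by less than 1.51-fold as well. Dbp, a transcription factor gene under direct clock control, had 36.2 FPKM in replicate 5 and 12 to 18.4 elsewhere. Npas2, a partner of Bmal1, had 8.0 in replicate 5 and 3.47 to 4.55 elsewhere. Per1 ranged from 7.57 to 10.5, Per3 from 3.77 to 5.51, Cry1 from 2.60 to 4.48, Nr1d1 from 22.1 to 32.4 and Nr1d2 from 19.0 to 25.2. Ciart ranged from 2.80 to 5.15, Bhlhe40 from 26.6 to 49.9, Bhlhe41 from 5.70 to 7.67, Nfil3 from 1.54 to 3.06 and Rora from 0.629 to 1.94. As a list, the clock genes passed neither the variability test (adjusted p = 0.0913) nor the co-variation test (adjusted p = 0.0596) against matched random lists. Both measures still lay high among the random lists, at percentiles 96.3 and 95.8.

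The 2 gene lists that differed most between libraries were markers of brain regions next to the hippocampus (median SD 0.73 on log2(FPKM + 1)) and of choroid plexus and ependyma (0.56), followed by blood cell genes (0.43). Of 28 lists with at least 5 measured members, 19 were more variable than random lists matched on level and 1, the nuclear genes of the mitochondrial respiratory chain, was less variable (median SD 0.08 on log2(FPKM + 1), adjusted p = 0.0319). Co-variation within the list passed its test in 19 of the 28. Both tests set a list against 10000 random lists, describe these libraries only, and were adjusted by the Benjamini-Hochberg method over the lists. The clock, cytokine and NF-kB, interferon, astrocyte, and monoamine receptor and neurotrophin lists passed neither test.

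**Figure D2:**
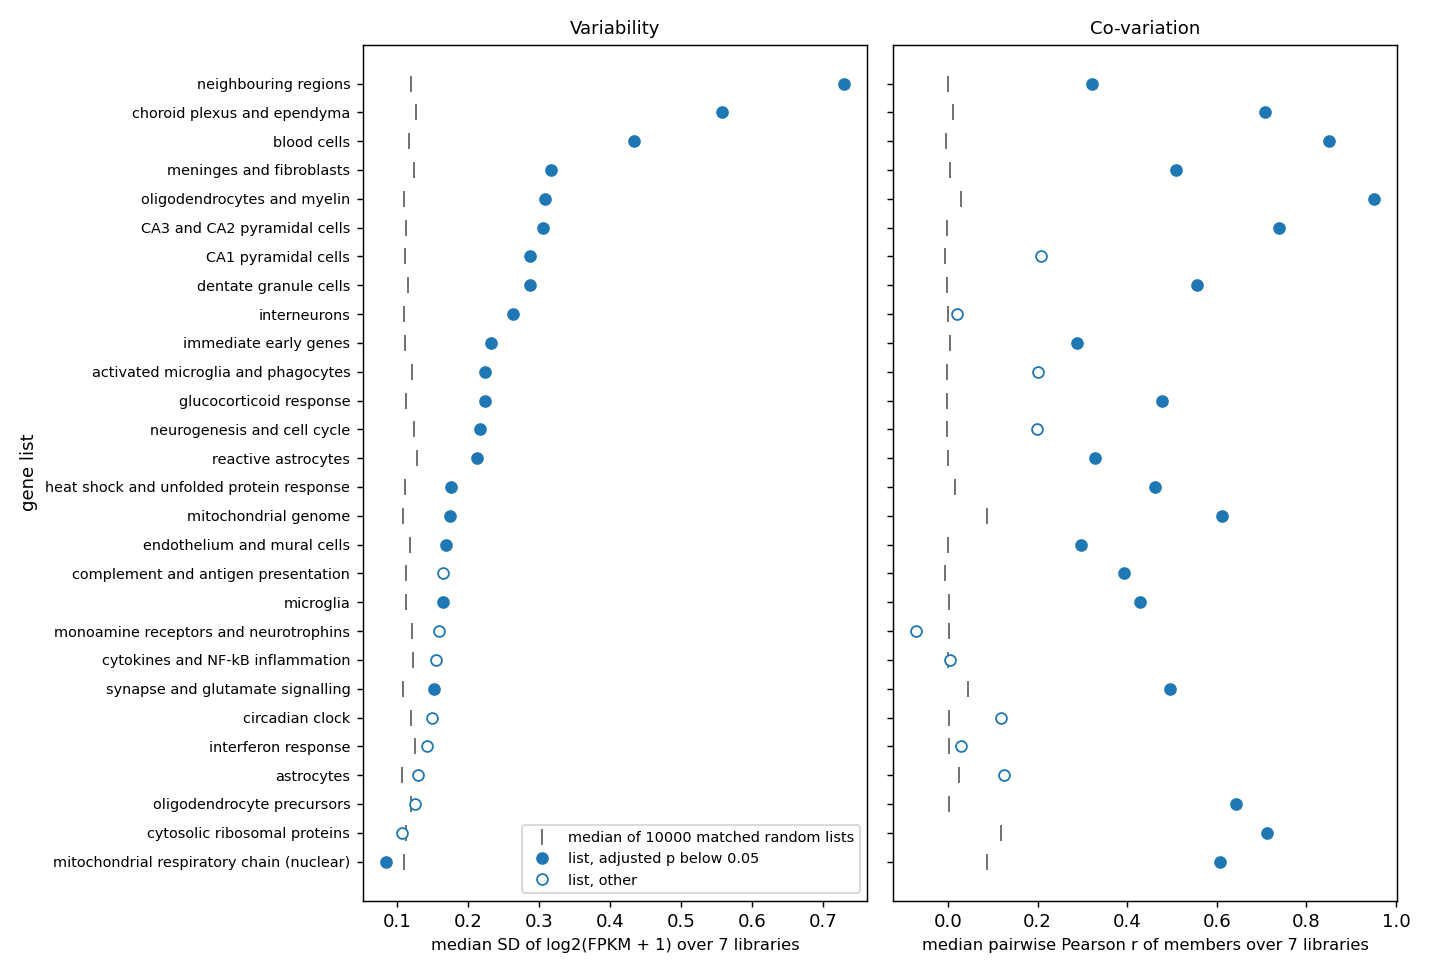
Median SD of log2(FPKM + 1) (left) and median pairwise Pearson r of members (right) for 28 gene lists over 7 hippocampus libraries; filled points have an adjusted p below 0.05, and ticks are the median of 10000 matched random lists. Neighbouring regions had the largest median SD, 0.73, and oligodendrocytes and myelin the largest median r, 0.951.

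Genes of striatal projection neurons stood far higher in replicate 5 than in the other 6 libraries. Penk, an opioid peptide precursor gene, had 521 FPKM there and 12.4 to 20.1 elsewhere, and Ppp1r1b, which encodes the dopamine-regulated phosphatase inhibitor DARPP-32, had 502 and 18.8 to 27.5. The sodium channel subunit gene Scn4b (181), the tachykinin gene Tac1 (103), Pde1b (218), Rasd2 (124), Pde10a (34.2), Rgs9 (32.8), Coch (25.6), Rasgrp2 (18.5) and Rarb (17.6) were likewise highest there and belonged to the 15 most variable genes. The neighbouring-regions list, which holds several of these, had a median SD of 0.73 (adjusted p = 0.000509). The dopamine receptor genes Drd1 and Drd2, at 46.4 and 44.5 FPKM in replicate 5, and Adora2a, at 61.6, have medians under 1 and were named after their values were seen.

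Most marker genes of the hippocampal fields were lowest in replicate 5: 9 of 13 dentate granule cell genes, 6 of 10 CA1 genes and 8 of 11 CA3 and CA2 genes. C1ql2 of dentate granule cells had 17.2 FPKM there and 27.8 to 48.2 elsewhere, and Lct had 3.69 and 6.93 to 11.4. In CA1, Lefty1 had 3.09 against 5.96 to 7.56 and Gpr161 4.12 against 9.07 to 12.4. The lists of dentate granule cells (median SD 0.29), CA1 (0.29) and CA3 and CA2 pyramidal cells (0.31) were each more variable than random lists, with an adjusted p of 0.000509, the smallest reached. Dock10 of the dentate list (8.75 to 10.8), Pou3f1 of the CA1 list (18.3 to 22.7) and Rgs14 of the CA3 and CA2 list (33.0 to 41.4) varied least. Pcp4, which the striatum and thalamus also express, ranged from 167 to 1118 and was highest in replicate 5. Of the synapse list, Slc17a7, the vesicular glutamate transporter gene, had 215 in replicate 5 and 383 to 475 elsewhere, Camk2a 446 and 543 to 801, and Nlgn1 ranged from 4.86 to 5.52.

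Choroid plexus and thalamic transcripts also differed between libraries, in another order. Ttr, the transthyretin gene of choroid plexus epithelium, had 18.0, 63.7, 822, 22.2, 60.2, 238 and 1073 FPKM in replicates 1 to 7. Ecrg4 was 16.4 in replicate 3, 17.4 in replicate 7 and 1.15 to 4.61 elsewhere, while Foxj1 of the same list ranged only from 1.61 to 4.98. The choroid plexus and ependyma list had a median SD of 0.56. Tnnt1 and Prkcd, both strongly expressed in thalamus, ranged from 0.314 to 13.6 and from 3.50 to 30.7. Calb2, a calcium-binding protein gene, reached 32.0 in replicate 3 and 29.0 in replicate 7 and 14.8 to 17.4 elsewhere. In the meninges and fibroblast list (median SD 0.32), Igf2 ranged from 4.24 to 14.4 and Slc13a4 from 0.523 to 2.73, while Lum ranged from 1.15 to 1.89. Haemoglobin genes Hbb-bs (45.3 to 158) and Hba-a1 (26.0 to 79.5), which mark blood, were highest in replicate 1.

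Oligodendrocyte genes moved together more tightly than any other list. The myelin list had a median pairwise r of 0.951 and a median SD of 0.31 (adjusted p = 0.00028 for co-variation). Ugt8a, which makes myelin galactolipids, ranged from 6.05 to 18.2 FPKM and Aspa from 5.90 to 15.6, while Mobp ranged only from 79.0 to 110. Oligodendrocyte precursor genes also co-varied (median r 0.643) without being more variable than random lists; Enpp6 ranged from 1.88 to 4.07, Bmp4 from 0.481 to 1.48 and Cspg4 from 2.37 to 2.75. Endothelial and mural genes co-varied (median r 0.298), with Acta2 at 4.17 to 9.75, Tagln at 2.92 to 8.30 and Abcb1a at 6.30 to 7.72. Interneuron genes were variable (median SD 0.26) without co-varying: Slc32a1, the GABA transporter gene, had 44.5 in replicate 5 and 16.5 to 18.6 elsewhere, while Sst ranged from 146 to 171.

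Glucocorticoid-response genes were variable and co-varying. The list had a median SD of 0.22 and a median pairwise r of 0.478. Plin4, a lipid droplet gene, ranged from 0.199 to 3.03 FPKM and Zbtb16, a transcription factor gene, from 3.25 to 14.0, while Klf9 ranged only from 57.7 to 72.6. Immediate early genes, which mark recent neuronal activity, were likewise variable (median SD 0.23) and co-varying (median r 0.287), with Fos at 5.91 to 14.9, Arc at 30.7 to 63.8 and Egr4 at 12.3 to 15.9. Heat shock and unfolded protein genes had a median SD of 0.18, with Hspa1b at 2.32 to 6.83, Sdf2l1 at 6.80 to 14.4 and Hsp90ab1 at 634 to 720.

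Inflammatory cytokine transcripts were close to the limit of detection in each library. Of 30 listed cytokine and NF-kB genes, 19 had a median FPKM under 1 and 14 stayed under 0.5 in each library. Il1b did not exceed 0.153 FPKM, an estimated 11 reads, Il6 an estimated 4 reads and Tnf an estimated 2 reads; these 3 were named after their values were seen, and differences between libraries in them were not tested. Among detected members, Ptgs2 ranged from 4.08 to 8.59, Il1r1 from 1.77 to 3.96 and Myd88 from 2.65 to 2.86. Microglial genes were variable (median SD 0.16, adjusted p = 0.0164) and co-varied (median r 0.430): Tyrobp ranged from 16.4 to 27.6, P2ry12 from 12.2 to 18.9 and Itgam from 5.0 to 6.48. Of 17 microglial genes, 10 were highest in replicate 5, the library with high striatal genes, and 6 in replicate 2. The share of all genes highest in these libraries was not computed. In replicate 4, 9 of the 17 were lowest, as were 15 of 20 ribosomal protein and 13 of 20 nuclear respiratory chain genes. Activated microglia genes were variable (adjusted p = 0.00302) without co-varying (adjusted p = 0.0748), with Cd63 at 29.6 to 49.8, Spp1 at 2.23 to 4.61 and Axl at 6.91 to 8.25. Complement and antigen presentation genes co-varied (adjusted p = 0.0124), with C4b at 3.80 to 7.67, Serping1 at 3.02 to 5.08 and B2m at 83.8 to 101. Reactive astrocyte genes passed both tests, with Serpina3n at 18.8 to 38.8, Gbp2 at 1.03 to 2.86 and S1pr3 at 1.35 to 1.86. In replicate 5, 6 of these 11 genes were lowest, against 26.0% of all genes kept. Aqp4 (20.3 to 43.1), Gjb6 (19.3 to 31.4) and Acsl3 (52.9 to 56.9) stand for the astrocyte list, and Ifitm3 (9.44 to 16.0), Isg15 (0.744 to 1.84) and Stat2 (4.02 to 4.82) for the interferon list.

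The remaining lists held receptors, new neurons and housekeeping genes. The serotonin receptor gene Htr1b had 8.02 FPKM in replicate 5 and 1.34 to 2.20 elsewhere, Htr2c ranged from 4.98 to 11.2 and the neuropeptide gene Vgf from 39.2 to 45.0. In the neurogenesis list, which was variable (adjusted p = 0.0168), Neurod1 had 4.44 in replicate 5 and 7.49 to 8.82 elsewhere. Igfbpl1 ranged from 0.962 to 1.65 and Cux2, a cortical marker of the neighbouring-regions list, from 1.63 to 2.62. Cytosolic ribosomal protein genes co-varied (median r 0.713) without being more variable, with Rps27 at 316 to 419 and Rpl4 at 347 to 404. Mitochondrially encoded genes passed both tests, with ATP6 at 92.3 to 189, ATP8 at 12.3 to 25 and ND5 at 3346 to 4198. Sdha (141 to 153), Ndufa1 (97.7 to 138) and Ndufa2 (82.4 to 109) are nuclear genes of the respiratory chain.

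The first principal component carried 49.6% of the variance and set replicate 5 apart. Its score was 28.7 for replicate 5 and -10.3 to 2.63 for the other libraries. The mean loadings of the neighbouring-regions and myelin lists lay at percentile 100 of matched random lists, and those of the dentate, CA1, blood and glucocorticoid lists at percentile 0. The second component carried 18.3%, with replicates 6 and 7 highest at 9.08 and 12.2, and the third 13.6%. Without replicate 5 the first component carried 40.8%.

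**Figure D3:**
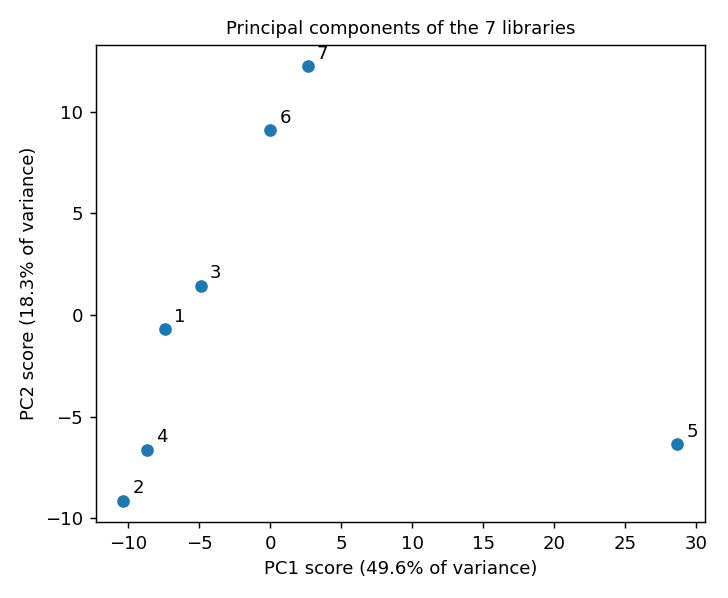
Scores of the 7 hippocampus libraries, numbered by replicate, on the first 2 principal components of log2(FPKM + 1), with the share of variance on each axis. Replicate 5 lies at 28.7 on the first component and the other 6 between -10.3 and 2.63.

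**Figure D4:**
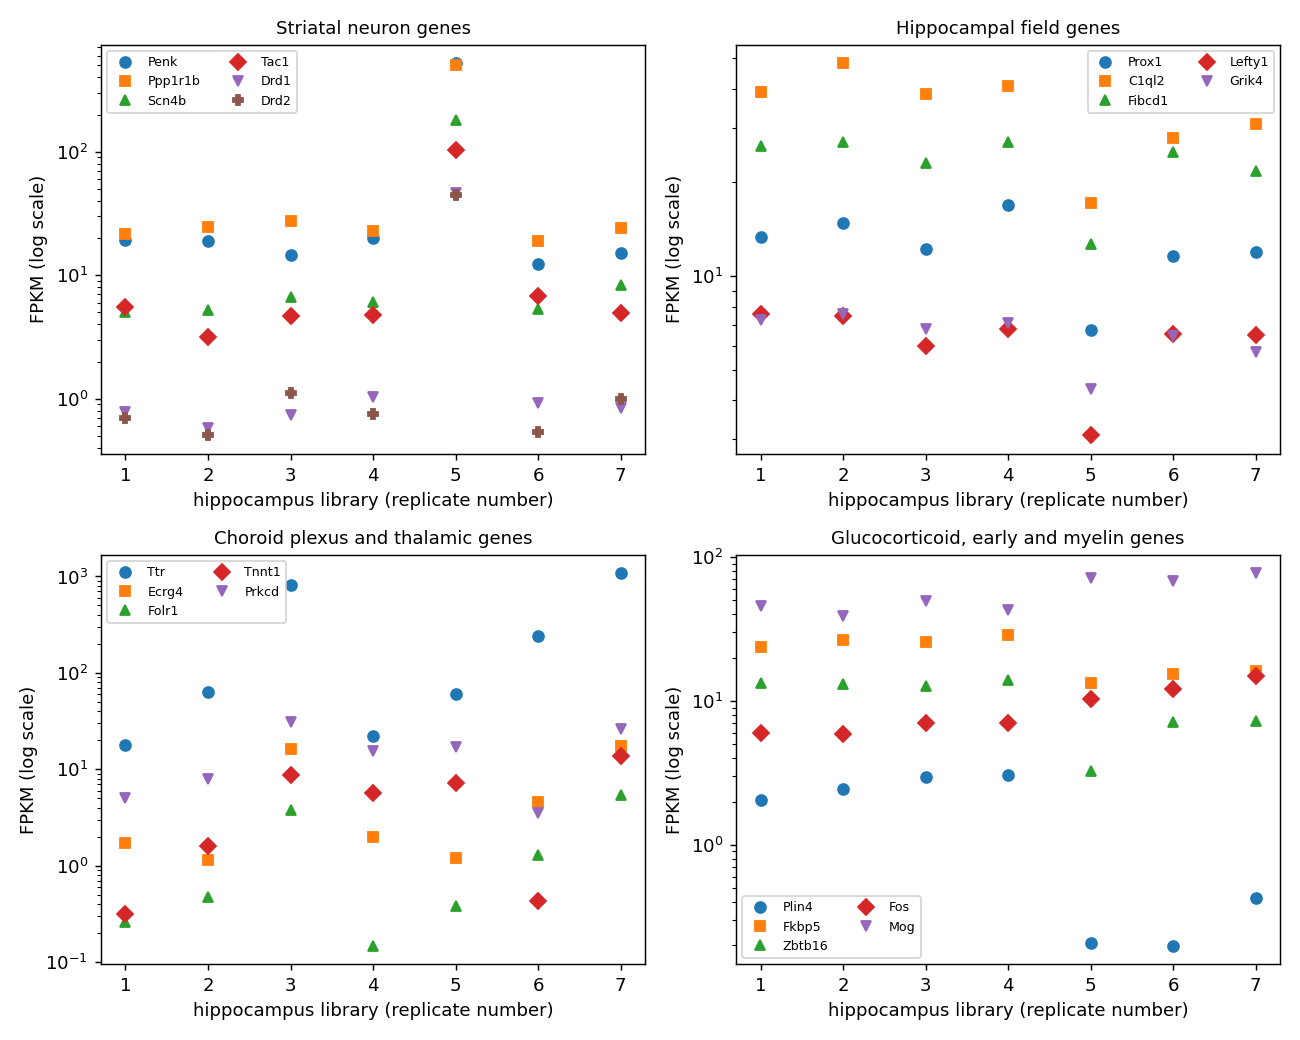
FPKM on log axes in each of the 7 hippocampus libraries for striatal, hippocampal field, choroid plexus and thalamic, and glucocorticoid, early and myelin genes, 1 symbol per gene. Penk reached 521 in replicate 5 and at most 20.1 elsewhere, and Ttr ran from 18.0 in replicate 1 to 1073 in replicate 7.

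The series title ties Per2 to neuroinflammation, and without condition labels the question that remained was whether Per2 moves with clock, inflammatory or cell type genes across libraries. The 7 Per2 values were separated by a gap that took 0.526 of their range, above the 0.510 that 95% of simulated normal sets stay under, with replicates 5 and 6 below it. A gap as large arose in 4.19% of simulated sets. With fewer than 6 libraries on either side, no pooled coefficient is given, and the counts of the planned tests below do not separate a relation with Per2 from a difference between the sets. By exact permutation of Pearson's r over all pairings, two-sided, 0 of 20 clock genes passed after Benjamini-Hochberg adjustment and 3 had an unadjusted p under 0.05 (Npas2, Csnk1d and Bhlhe40); by Spearman's rho 0 passed. Of 28 list scores 1 passed, dentate granule cells, with 9 at an unadjusted p under 0.05; by Spearman's rho 0 passed. The dentate call was lost without any one of replicates 1 to 6 (adjusted p from 0.0778 to 0.292 by exact permutation), after rescaling (0.0528) and under upper-quartile scaling (0.128). Its direction stayed positive in each alternative, and with 6 libraries a single list passes only at 0.00139, the smallest p that exact permutation can then give, so the losses with 1 library left out say little about stability; those under the other scalings, with 7 libraries, are not covered by this. Without replicate 3, and after rescaling, the CA3 and CA2 list passed instead. Activated microglia and phagocyte genes passed with a negative direction at a median FPKM minimum of 5 (adjusted p = 0.0262 by exact permutation), and myelin genes with a negative direction without replicate 7 (0.0389). A planned check left out replicates 5 and 6, the 2 libraries farthest from the median of Per2. In the 5 left, r was 0.803 for dentate, -0.760 for myelin, -0.784 for activated microglia, -0.755 for cytokine and -0.00311 for microglia scores. It was 0.757 for Csnk1d, 0.673 for Bhlhe40 and -0.561 for Npas2. The largest in size among lists was -0.994, for choroid plexus and ependyma. With 5 libraries and no p-value, these values are description only.

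Across genes, limma-trend called 0 of 12051 for an association with Per2 after Benjamini-Hochberg adjustment, with a smallest adjusted p of 0.113. At an unadjusted p under 0.05 there were 2458, and limma without the trend also called 0, with 2444 at an unadjusted p under 0.05. With the number of detected genes as covariate limma also called 0, and 297 had an unadjusted p under 0.05. Without replicate 5, and without the covariate, limma-trend called 0, and 1398 had an unadjusted p under 0.05. The 10 genes with the smallest p and a positive slope were Sipa1l3, Fbxo10, Tanc1, Wipf3, Syt7, Alox12b, Anxa11, Dagla, Rilpl1 and Epha10. All 10 were lowest in replicate 5, which had the lowest Per2 and also stood apart on striatal genes. Sipa1l3 ranged from 6.94 to 16.4 FPKM, Wipf3 from 71.9 to 134, and Syt7, a calcium sensor gene of vesicle release, from 18.5 to 32.1. The 10 with a negative slope were Gamt, Nts, Cerox1, Ddit4l, P2ry12, Gm53208, Immp1l, Cox7a1, Sytl2 and Gnb4. Gamt, Cerox1, Ddit4l, P2ry12 and Gnb4 were highest in replicate 5 and the others in replicate 6. Gamt, a creatine synthesis gene, ranged from 8.90 to 15.6, and Nts, the neurotensin gene, from 5.26 to 11. Adjusted over the list alone, 14 of 15 myelin genes passed with a negative slope and 9 of 13 dentate genes with a positive one. Of 16 glucocorticoid genes 10 passed, 9 of them positive. Members of these lists co-vary, so the counts are not independent findings. By exact permutation the dentate list score passed, and those of the myelin and glucocorticoid lists did not (adjusted p = 0.137 and 0.128). With camera's preset correlation 11 of the 28 lists passed; with an estimated correlation 0 did (smallest adjusted p = 0.423 with an estimated correlation). Without replicate 6 limma called 1115 genes, but replicate 5, apart on the first principal component, was then the only library below the Per2 gap.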

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

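Chosen only after the result was seen were the tests of the wrong label and of unchanged tissue in the first pattern, the share of all genes that follow Ttr, and the fold range of the glucocorticoid list; the other tests were set before. A library was singled out where its gap to the nearest one, over the range, passed Dixon's 95% critical value for 7 values. This gap ratio was taken on FPKM for genes, without the log, and on log2-based scores for lists. Without the log, high values stand apart more easily, and the gap ratios were not recomputed on log2(FPKM + 1). With normal values, chance gives such a gap in about 1 in 20 measures. Of 12052 genes, 1171 (9.72%) passed the critical value, 839 of them in replicate 5. Among the genes named by rule 23 met it, 22 of them in replicate 5 (17 highest, 5 lowest); since the rule favours variable genes, the chance rate does not apply to them.

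Striatal neuron genes stood apart in replicate 5: Rgs9 (gap ratio 0.986), Penk (0.985), Scn4b (0.982), Ppp1r1b (0.982), Pde10a (0.972), Tac1 (0.964), Rarb (0.960), Pde1b (0.959), Rasd2 (0.95), Rasgrp2 (0.955), Coch (0.875) and Pcp4 (0.733). A candidate explanation is striatal tissue in the dissected sample: of 15 further striatal genes, 14 (93.3%) were highest and apart there. A whole striatal library under a wrong label is argued against, since 34 hippocampal field genes kept a median of 0.638 of their level in the other libraries (quartiles 0.520 and 0.866). A rise of striatal genes inside otherwise unchanged hippocampus is argued against too: 67.6% of those field genes were lowest in replicate 5 against 26.0% of all genes, and their upper quartile of 0.866 lay below the lower quartile of all genes, 0.895. A condition of the animal as explanation was not tested, since the labels name none.

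Other genes apart in replicate 5 were Slc32a1 (0.925), Htr1b (0.873), Npas2 (0.763), Dbp (0.738) and Nr1d2 (0.575), all highest there, and Neurod1 (0.697), Slc17a7 (0.648), Lefty1 (0.642), Il1r1 (0.640) and Gpr161 (0.596), all lowest there. Gbp2 was highest and apart in replicate 4 (0.614). The astrocyte list score (0.770) and the endothelial and mural list score (0.610) were apart in replicate 1.

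Choroid plexus and thalamic genes differed between libraries, with Ttr from 18.0 to 1073 FPKM. Choroid plexus carried over in dissection is a candidate explanation: 7 of 10 further choroid plexus genes (70%) had a Spearman rho of at least 0.7 with Ttr. For thalamic tissue the share with Tnnt1 was 6 of 9 (66.7%), just under the 70% set for it, so that this stays open. A change of Ttr alone in hippocampal cells is argued against: the 70% of further choroid genes that followed Ttr, with a 95% Wilson interval from 39.7%, compare with 5.04% of all genes that reached an FPKM of 1. The interval treats the 10 genes as independent, which co-varying genes are not, so it may be too narrow. The median range of the further choroid genes does not decide the question, at 2.03 on log2(FPKM + 0.1), with quartiles 1.38 and 2.73, and 0.93 on log2(FPKM + 1).

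In the glucocorticoid-response list 3 of 16 members, Plin4, Fkbp5 and Cdkn1a, showed a gap above 0.510 of their range. The gap set replicates 5, 6 and 7 apart in Plin4 and Fkbp5, but replicates 2, 3 and 4 in Cdkn1a. Plin4 had 2.04, 2.43, 2.98, 3.03, 0.207, 0.199 and 0.429 FPKM in replicates 1 to 7. Glucocorticoid signalling that differed between animals is a candidate explanation: the mean correlation of 17 further glucocorticoid genes with the list score lay at percentile 100 of matched random lists, although Nedd9 went the other way and Agt, Arl4d and Mt2 hardly followed. The random lists were matched on level and not on co-variation, so any cause shared by both lists could give this percentile. All 7 libraries were used for it, replicate 5 included. Tissue makeup stays open: without replicate 5, reactive astrocyte and dentate lists followed Plin4 (rho 0.943 and 0.771), precursors ran opposite (-0.714), and the largest median fold range among these lists, 1.57, was similar to the 1.5 of the glucocorticoid list. Plin4 itself ranged 15.3-fold there, but as the most variable member it does not decide for the list. The astrocyte list did not follow Plin4 there (rho -0.2, median fold range 1.24), so the reactive list need not reflect the share of astrocytes. Injury, handling and time of day stay open and untested.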

How the results depend on the processing

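The filter on mean FPKM was chosen after seeing the data; the other alternatives were planned. Those for injury against control were not run, because no label gives a condition. No paired analysis was possible because there is 1 group. The Per2 ratio moved by less than its spread in each alternative. Lists past the variability test in either direction numbered 20 in the main setting, 19 more variable and 1 less variable. With 1 library left out they numbered 16 to 22, and co-varying lists 18 to 21. In each alternative these counts stayed within 1.5 times the main 20 and 19. For clock genes with Per2 the count was 0 of those past the filter in each alternative. For list scores with Per2 the main count of 1 became 0 with Spearman's rho and with upper-quartile scaling and 2 with a minimum of 5, and ran from 0 to 2 when 1 library was left out; the cause was not tested. The limma count of 0 became 1115 without replicate 6 (675 positive, 440 negative) and was 0 in the other leave-one-out fits. Without replicate 6, replicate 5 alone lay below the Per2 gap, at 4.53 FPKM against 5.78 or more elsewhere. That fit therefore does not separate a relation with Per2 from the difference of replicate 5, and the cause was not tested. The first component ran from 40.8% without replicate 5 to 55.9% without replicate 7.

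The median pairwise r of the blood list fell from 0.850 to -0.0205 with a minimum of 0.1, which also admits members near the floor. Lists with a median r near 0 changed sign in places; the cause was not tested in either case. Under rescaling the monoamine list had 0.0154. Under upper-quartile scaling the cytokine list had -0.00619 and the interferon list -0.0329. With a minimum of 0.1 the cytokine list had -0.0341 and the monoamine list 0.0261, and with a minimum of 5 the cytokine list had -0.178 and the interneuron list -0.107. When 1 library was left out, the cytokine list ran from -0.0516 to 0.0598, the astrocyte list from -0.0790 to 0.215, and the interferon list from -0.140 to 0.0701. The interneuron list ran from -0.0377 to 0.116 and the monoamine list from -0.156 to 0.0273. Of these lists only the blood list had passed the co-variation test. Depth limits genes near the floor, such as Il1b, Il6 and Tnf.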

Other observations

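The tests of the dentate genes and of the reassigned Per2 values were set before their results were seen; the genes named here were chosen after. Fkbp5, a glucocorticoid receptor co-chaperone gene, had 23.8, 26.7, 25.8, 28.7, 13.3, 15.4 and 16.1 FPKM in replicates 1 to 7, and Xdh, the xanthine dehydrogenase gene, 2.04, 2.41, 2.04, 2.38, 0.718, 0.635 and 0.796. Opalin, a myelin gene, had 11.8, 9.56, 12, 9.79, 19.5, 18.2 and 19.9. Lcn2, an acute-phase gene, had 14.3 FPKM in replicate 2 (an estimated 455 reads) and at most 0.653 elsewhere. The class II antigen presentation gene Cd74 had 5.15 in replicate 4 and at most 2.06 elsewhere, and H2-Aa, H2-Ab1 and H2-Eb1 were also highest there, at 2.17, 1.74 and 1.78.

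A gap above 0.510 of the range occurred in 568 of 12052 genes (4.71%), close to the 5% that chance gives. Among the 56 ways to part 7 libraries so, the smaller set was replicates 5, 6 and 7 in 59 genes, replicates 2 and 3 in 55 and replicates 2 and 4 in 42. Of those with replicates 5, 6 and 7, 17 had a gap of at least 0.3 on the log2 scale, against 5 for replicates 3 and 7 and 4 for replicates 5 and 7, the next by this measure. At the 99th percentile of simulated gaps the order changed: 12 genes parted replicates 2 and 3 and 8 parted replicates 5, 6 and 7. Per2 itself parted replicates 5 and 6 from the rest. No condition is read from these sets, and they were neither averaged nor tested.

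One hypothesis was that the Per2 level follows the share of dentate granule cells. The mean correlation of 7 further dentate genes with Per2 lay at percentile 99.4 of matched random lists, as it may under this hypothesis, although Synpr and Spata13 ran the other way. In checks chosen after this was seen, the percentile was 99.97 without replicate 5 and 99.93 without replicates 5 and 6. This remains a hypothesis, found and tested on the same libraries. The random lists were matched on level and not on the co-variation of dentate genes. Scores of the CA3 and CA2, synapse, glucocorticoid and reactive astrocyte lists also rose with Per2 at an unadjusted p under 0.05 by exact permutation. Over all 7 libraries the relation is thus not particular to dentate genes. Without replicates 5 and 6, r with Per2 was 0.803 for the dentate score and 0.912 for the synapse score. It was 0.418 for CA3 and CA2, 0.297 for glucocorticoid and 0.0814 for reactive astrocyte scores. These values rest on 5 libraries and were not tested. Chance order of the Per2 values as the source of the 2458 genes at an unadjusted p under 0.05 was tested with 100 reassignments: 2 gave as many, with 2686 as the highest and 447 as the median. Chance order alone is thus argued against for the main fit, which does not single out Per2 as the measure the genes follow. The count fell to 1398 without replicate 5, where no reassignments were run. With the number of detected genes as covariate 297 genes were left, and 72 of the same 100 reassignments in that fit gave as many (median 456), so that chance order is not excluded there; this check was chosen after the result was seen.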
